A study of Rattus norvegicus with 8 samples.

How the data were processed

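Single-cell RNA sequencing was done on cells from the fracture callus, the repair tissue that bridges a broken bone, of Sprague Dawley rats. Per the labels' protocols, callus tissue was digested with collagenase A for 4 h, and the released cells were kept in a culture dish for 24 h before libraries were made. Cells that attach and survive in the dish are therefore what was measured. Per the series' design text, 10000 cells were used for each library with the 10x Chromium V3 chemistry, in which each captured transcript carries a unique molecular identifier (UMI). The deposited table for CGRP at week 12 held 10670 barcodes, more than this number, and the reason is not given in the sources used here. Zoledronate, a nitrogen-containing bisphosphonate that inhibits bone resorption, was injected under the skin each week at 0.3 mg/kg, and the femur was fractured after 12 weeks of injections, per the labels. The labels name a steel and a magnesium-containing nail for fixation, but do not say which group had which nail, nor the dose or route of CGRP (calcitonin gene-related peptide, a neuropeptide). The number of animals behind each library is not given in the sources used here.

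The authors deposited 1 table of counts per library, with genes as rows and cell barcodes as columns, and the values were whole numbers of UMIs. STAR was the aligner and Rnor_6.0 the genome build, per the submitters' processing notes. The version of STAR, the gene annotation, the cell calling and the filters on cells and genes are not given in the sources used here. In the tables as deposited, every listed gene was seen in at least 5 cells of its library, every cell had at least 500 genes, and 0 mitochondrially encoded genes were listed. A gene that is not listed in a library can therefore still have had a few UMIs, so no limit from a count of 0 was computed for it. Damaged cells could not be judged by their mitochondrial share. Gene symbols were used as the tables give them. The reference table at hand was of another assembly, GRCr8, so no coordinates are given.

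Each group of treatment and week is 1 library, so no test, p-value or standard error was computed between libraries. Counts of genes past a fold describe size in these libraries and are not counts of changed genes. Differences are given as both values, with exact Poisson 95% intervals for sums of UMIs and exact Clopper-Pearson 95% intervals for shares of cells. These intervals cover counting error only, not the spread between animals, dishes or libraries. For sums, each UMI is treated as an independent draw, so the spread between cells is not covered either. An additive model of treatment and week was not fitted, because its error term would have been the difference between weeks that the design compares. The comparisons, gene lists, cell type markers, naming rule and alternatives were fixed before the data were examined, except where a choice is said to have been made later.

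Cells needed at least 500 UMIs, 200 genes and at most 20% mitochondrial UMIs, a filter that removed 0 of the 69624 barcodes. Scrublet, run per library through scanpy 1.11.5, called 21 barcodes (0.0302%) doublets, which were removed. A caller that marks so few of this many cells was taken not to have worked. Whether doublets were removed before deposit is not given in the sources used here, so they were treated as still present. The remaining 69603 cells were scaled to 10000 UMIs and log-transformed, 2000 highly variable genes were chosen with library as the batch key, and 30 principal components with 15 neighbours went into Leiden clustering at resolution 1 (leidenalg 0.10.2, igraph 0.11.9). Clusters whose median UMI count was under 1/3 of the median of their own libraries were left unnamed and kept out of the ratios. The remaining cells are called full-depth cells. Clusters were to be named from 21 fixed lists of 10 markers each, and genes were to be compared within a mesenchymal and a macrophage compartment. Each of the 14 full-depth clusters had 6 to 9 of the 10 fibroblastic markers in at least 25% of its cells. Among their 10 leading genes, however, 3 clusters had a fibroblastic marker, 5 had a marker of another class and 0 of the fibroblastic class, and 6 had no marker. The macrophage compartment held no cluster, and clusters were left unnamed. Genes were therefore compared between libraries over all full-depth cells, and cluster sizes were not compared between groups.

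For each library the UMIs of a gene were summed over the full-depth cells and scaled to a sum of 1000000 (CPM). Log2 ratios were taken of CPM plus 1, which makes the ratio of a gene near 1 CPM smaller than the ratio of its counts. Named genes had a mean of at least 50 CPM and at least 50 UMIs over the 2 libraries at each week, and were at least 1.5-fold higher or at least 1.5-fold lower at both weeks. They were ranked by the smaller absolute log2 ratio, and the first 5 in each direction were named. Where fewer than 3 passed, the first 3 of each week alone were named. For week 12 against week 4 the same rule was applied over the 4 treatments. Ribosomal protein, haemoglobin and immunoglobulin genes, mitochondrially encoded genes and genes with no symbol stayed out of the ranking. Up to 4 members of each list with the largest absolute log2 ratio could be named too, and Calcrl, Ramp1, Fdps, Trpm7, Acp5 and Ctsk were always given. Genes outside the rule are said to have been chosen after their values were seen.

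For each of 25 fixed gene lists the median log2 ratio was taken over members with at least 20 UMIs in the 2 libraries together. Its percentile among 10000 random lists of the same size, matched on mean expression in 20 bins, describes these libraries and is no test. Medians were given for lists with at least 3 such members. The list of mitochondrially encoded genes had none, which left 24 lists. Shares of cells with a UMI of a gene were compared after each cell was thinned to 1000 UMIs.

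Alternatives fixed beforehand for the ratios and lists were edgeR's TMM factors (edgeR 4.0.16), DESeq2's size factors (DESeq2 1.42.0), equal weight for each cell, thinning to 1000 UMIs, a stricter cell filter (1000 UMIs, 500 genes, 10% mitochondrial UMIs), and other minimums of UMIs. For the shares of cells they were every barcode, the stricter filter, Leiden resolutions 0.5 and 2, 4000 highly variable genes, 15 principal components and doublets kept. Keeping the low-count clusters in the ratios and thinning to 5000 UMIs were chosen after seeing the data. The steps were tested on counts simulated for the zoledronate and control libraries of week 4, over 12282 genes of which 200 were changed. Genes raised 2-fold had a median log2 ratio of 0.96, genes lowered 2-fold one of -0.91, and unchanged genes one of 0.00. The raised list came out at percentile 100 and the lowered list at percentile 0, 4 of 100 lists of unchanged genes fell outside the central 95%, and 96.5% of the intervals of ratios held the true ratio. The counts were Poisson draws from 1 shared profile, with no spread between cells, animals or libraries, and the lists were of randomly chosen genes. The simulation thus checks the arithmetic only. It cannot show how the intervals or percentiles behave for real libraries or for genes that vary together. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, matplotlib 3.10.9 and R 4.3.3.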

Results

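Callus cells of fractured rat femora were sequenced from 4 treatments at 4 and 12 weeks after fracture, with 1 library per treatment and week. The treatments were control (untreated per the labels), zoledronate, zoledronate with CGRP, and zoledronate with magnesium. The last pair are called the CGRP and the magnesium libraries. The series title asks whether magnesium helps a femur to heal after the kind of fracture that long bisphosphonate use can bring. The tables held 7541 and 8429 cells for control, 8028 and 9802 for zoledronate, 8730 and 10670 for CGRP, and 8228 and 8196 for magnesium, at weeks 4 and 12. Total UMIs at the 2 weeks were 149861388 and 141264724 for control, 157666295 and 157110673 for zoledronate, 158882321 and 147926711 for CGRP, and 152287764 and 160177900 for magnesium. The median per cell lay between 12544 (CGRP, week 12) and 19852 (control, week 4). At this depth the 95% intervals of the expression values named here reached at most 2.38% from any value of 50 CPM or more, and at most 7.70% from any value of 5 CPM or more. With no replicate, the libraries can be compared but not the treatments, and higher and lower below refer to libraries.

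Collagen and other fibroblastic genes were widely detected in every library. Of the 16 clusters, the 14 with full-depth cells each had 6 to 9 of the 10 fibroblastic markers in at least 25% of their cells, among them the collagen genes Col1a1, Col1a2 and Col3a1. Col1a1, the main collagen of bone and fibrous tissue, was at 13008 to 23687 CPM. These genes set few clusters apart: only clusters 0, 5 and 9 had a fibroblastic marker (Lum or Dcn) in their 10 leading genes. Clusters 0, 1 and 8 had a chondrocyte marker there (Comp, Acan and Hapln1), clusters 4, 6 and 14 had Il1rl1 from the mast cell list, cluster 4 also had Acta1 from the muscle list, and the other 6 had no marker of any class, so no cluster was given a cell type. No cluster had a marker of macrophages, osteoclasts or endothelial cells in its 10 leading genes. Csf1r, the receptor that macrophages need, was at no more than 0.526 CPM, and Ptprc, which marks blood cells, was listed only in the zoledronate (0.0578 CPM) and CGRP (0.0746 CPM) libraries of week 12. Bglap (osteocalcin), a gene of mature bone cells, was at no more than 0.203 CPM. Cartilage genes differed: Col2a1, the collagen of hyaline cartilage, was at no more than 0.0739 CPM, while Sox9, the transcription factor of chondrocytes, was at 55.6 to 106 CPM at week 12 and the cartilage matrix gene Hapln1 reached 111 CPM in CGRP at week 4. Runx2, the early bone cell transcription factor, was at 18.8 CPM in the zoledronate library of week 12 and 17.2 CPM in the control library of week 4. Clusters were often made of 1 library: cluster 5 took 97.7% of its cells from zoledronate at week 12, cluster 9 took 98.3% from CGRP at week 12, cluster 8 took 92.6% from CGRP at week 4, and cluster 4 took 91.3% from control at week 12. Because these clusters followed the library, expression was compared over all 65115 full-depth cells, 93.6% of the cells clustered. Cells of 2 low-count clusters stayed out. Their share of a library at week 4 was 10.4% in control (95% interval 9.70 to 11.1), 4.96% in zoledronate (4.50 to 5.46), 8.17% in CGRP (7.60 to 8.76) and 12.6% in magnesium (11.9 to 13.4). At week 12 it was 8.54% (7.95 to 9.15), 5.14% (4.71 to 5.60), 1.61% (1.38 to 1.87) and 1.95% (1.66 to 2.28) in the same order.

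The first comparison set zoledronate against no treatment. Genes of dividing cells were lower in the zoledronate library at both weeks, and by more at week 12. Mki67, the standard marker of proliferating cells, stood at 122 CPM in control and 72.3 CPM in zoledronate at week 4, and at 96.5 and 15.5 CPM at week 12 (log2 ratios -0.75 and -2.57). Postn, which encodes the matrix protein periostin of periosteum and healing bone, was higher, at 339 against 104 CPM at week 4 and 630.2 against 265 CPM at week 12. Genes of the sterol pathway that zoledronate blocks were lower at both weeks, and matrix genes of fibrous tissue, led by the proteoglycans decorin (Dcn) and lumican (Lum), were higher at week 12.

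All 20 members of the cell cycle list were lower in zoledronate at both weeks, with a median log2 ratio of -0.55 at week 4 and -2.19 at week 12. Both medians lay at percentile 0 of the random lists. By size, 7 members were at least 1.5-fold lower at week 4, and 19 were at least 2-fold lower at week 12. Of the 9 genes that met the naming rule as lower at both weeks, the first 5 were of this kind: Mki67, the kinetochore gene Cenpf (-0.72 and -2.67), the mitotic cyclin Ccnb1 (-0.71 and -2.72), the cytokinesis gene Prc1 (-0.71 and -2.60) and Cks2 (-0.63 and -2.19), a partner of cyclin-dependent kinases. The share of full-depth cells with a UMI of Mki67, after thinning to 1000 UMIs, was 7.22% (6.65 to 7.82) in control and 0.914% (0.731 to 1.13) in zoledronate at week 12, and 8.02% and 5.14% at week 4. Unthinned, it was 37.9% and 6.25% at week 12, and 34.6% and 22.5% at week 4. No class of cells that should lack Mki67 was at hand to measure its background from free RNA.

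By the rule, 13 of 2167 genes were higher in zoledronate at both weeks. In ranked order they began with Postn (1.69 and 1.25), Igfbp3, a carrier of insulin-like growth factors (1.28 and 1.18), and Rasl11b (0.83 and 1.13). Next were the LIM domain gene Csrp2 (0.82 and 1.18) and Cilp2 (0.81 and 3.07), a gene of the cartilage intermediate layer protein family. Of the 16 measured genes for fibrous matrix, 9 were at least 1.5-fold higher at week 12 (median 0.65), while the median at week 4 was 0.01. Dcn was at 355 CPM in zoledronate and 2.19 CPM in control at week 12, and Lum at 139 and 6.02 CPM. The control library of week 12 was the low side of both: at week 4 control had 147 CPM of Dcn and 192 CPM of Lum. Of the 22 genes for mevalonate and cholesterol synthesis, 21 were lower at week 4 (median -0.17) and 19 at week 12 (median -0.52), where Hsd17b7 (-1.06), Msmo1 (-1.04), Mvd (-0.98) and Cyp51 (-0.80) were the lowest. Fdps, the farnesyl diphosphate synthase that zoledronate inhibits, was at 385 against 475 CPM at week 4 and 276 against 369 CPM at week 12.

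Among genes by which stromal cells act on osteoclasts, Csf1, the growth factor of the macrophage lineage, was lower in zoledronate at week 12 (-1.74), as was Lgr4 (-1.34), while Il34, another ligand of the same receptor as Csf1, was higher (0.95). Of the 6 measured members 4 were lower and 2 higher, and the list median of -0.45 lay within the central 95% of random lists (-0.51 to 0.22). Acp5 and Ctsk, 2 enzymes of bone-resorbing cells, were higher at week 12 (Acp5 16.9 against 7.62 CPM, Ctsk 124 against 50.8 CPM), in libraries with no osteoclast cluster. At week 4 Ctsk was at 126 CPM in zoledronate and 115 CPM in control, so control at week 12 was its low side. Hypoxia genes were higher at week 12 (median 0.47), with Bnip3 at 2.06 and Hif1a at 1.21, and 12 of 14 genes of the unfolded protein response were higher (median 0.36). For week 12 over week 4 the hypoxia median was -0.27 in control and 0.25 in zoledronate, so both libraries differed from their own week 4. Interferon response genes had medians of -0.14 and -0.46, with Cxcl10 at -1.73 and Usp18 at -1.27 at week 12. The inflammatory macrophage list had a median of -0.93 at week 12, but its chemokine Ccl2, which attracts monocytes, was higher at both weeks (1.15 and 2.00). Medians for bone matrix (0.01 and 0.28), cartilage (-0.11 and 0.34) and the immediate early and heat shock list (-0.05 and -0.42) are set out in the plot of list medians. Scaling mattered at week 12: the median of all genes was -0.09, and TMM factors added 0.14 to the log2 ratios of well expressed genes and DESeq2's factors 0.13, so the sizes at week 12 depend on the scaling. The osteoclast resorption median (-0.0047) turned to 0.013 with TMM factors. The log2 ratios of all genes had a standard deviation of 0.21 at week 4 and 0.52 at week 12.

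**Figure D1:**
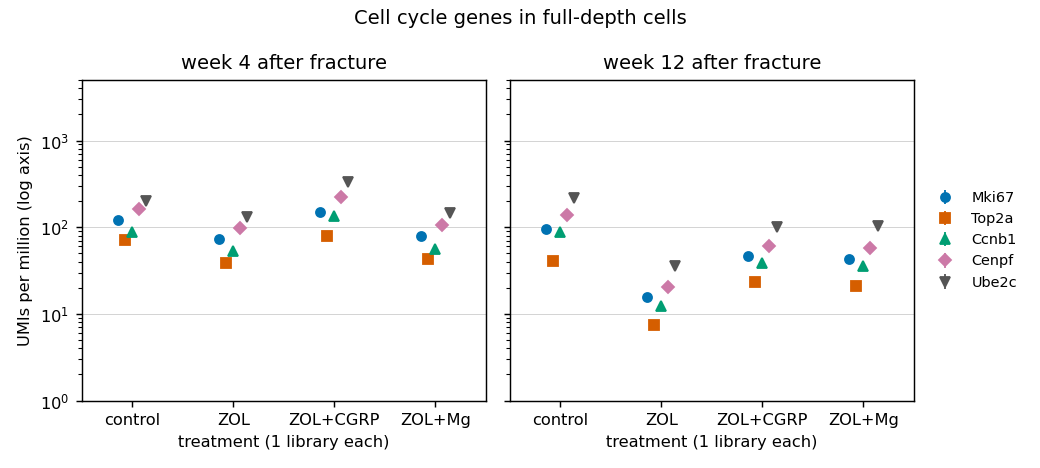
Expression of 5 cell cycle genes (CPM, log axis) in full-depth cells of the 4 treatments (1 library each) at weeks 4 and 12, with exact Poisson 95% intervals, which are mostly smaller than the symbols. At week 12 the zoledronate library was lowest for every gene drawn, with Mki67 at 15.5 CPM against 96.5 CPM in control, 46.1 CPM in CGRP and 43.3 CPM in magnesium.

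The second comparison asked how adding CGRP to zoledronate differed from zoledronate alone. Cell cycle genes were higher in the CGRP library at both weeks, with Mki67 at 150.2 against 72.3 CPM at week 4 and 46.1 against 15.5 CPM at week 12. Ccnd1, the cyclin that drives entry into the cell cycle, was higher too, at 223 against 66.7 CPM and 95.8 against 39.7 CPM. Fibrous matrix genes were lower in CGRP at week 4, with Dcn at 9.32 against 134 CPM and Lum at 21.7 against 168 CPM. Genes for stromal control of osteoclasts were higher at week 12, with Csf1 at 84.3 against 27.2 CPM.

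All 20 cell cycle genes were higher in CGRP at both weeks (medians 1.03 and 1.10), with 11 at least 2-fold higher at week 4 and 11 at week 12. Against random lists these medians lay at percentile 100. By the naming rule, 24 of 2101 genes were higher in CGRP at both weeks and 39 were lower. The higher genes began with the glutathione transferase Gsta1 (1.52 and 1.37) and the mitotic ubiquitin-conjugating enzyme Ube2c (1.36 at week 4, and 102 against 35.2 CPM at week 12). Next were Ccnd1 (1.73 and 1.25), the AP-1 transcription factor Fos (1.14 and 1.07) and the chromatin gene Hmgb2 (1.21 and 1.02). The lower genes began with Cilp2 (-1.82 and -2.66), the matrix gene Hmcn1 (-2.14 and -1.47) and Rasl11b (-1.61 and -1.44). Next were Cox6a2, the muscle form of a cytochrome oxidase subunit (-1.25 and -1.33), and the secreted factor C1qtnf3 (-2.89 and -1.07). Cilp2 and Rasl11b were among the genes that were higher in zoledronate than in control. The zoledronate library is shared by both comparisons, so a chance value in it would move them in opposite directions.

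Receptor genes for CGRP were close to the floor. Calcrl, the receptor subunit that binds the peptide, was at 0.0701 CPM in CGRP (0.0350 to 0.126) and 0.135 CPM in zoledronate (0.0832 to 0.206) at week 4, and at 0.502 CPM (0.394 to 0.630) and 0.141 CPM (0.0885 to 0.214) at week 12. Its partner Ramp1 was at 0.0574 and 0.0704 CPM at week 4, a difference not detectable at this depth, and at 0.0678 CPM in CGRP at week 12, where zoledronate did not list it. Ramp3, the partner that turns Calcrl into an adrenomedullin receptor, was higher in CGRP (1.69 and 1.53), and the list of CGRP and its receptors had medians of 0.03 and 0.25. Targets of cyclic AMP and CREB had medians of 0.41 and 0.32, with Nr4a1 (1.44), Areg (1.17) and Fos higher and Pde4d lower (-1.02) at week 4, and 12 of 13 members higher at week 12. The immediate early and heat shock list, which cell handling can raise and which shares Fos and Junb with these targets, was higher in CGRP too (medians 0.41 and 0.33).

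Of the 16 fibrous matrix genes, 10 were at least 1.5-fold lower in CGRP at week 4 (median -0.72), led by Dcn (-3.70), Lum (-2.90), Thbs2 (-1.83) and Postn (-1.69), and the median at week 12 was -0.04. WNT signalling genes were lower at week 4 (median -0.40), with the secreted modulator Dkk3 at -2.50 and Wnt16 at -2.37. At week 12 the WNT median was 0.10, within the central 95% of random lists (-0.13 to 0.21), with the WNT inhibitor Sfrp1 the furthest from 0 (26.9 against 1.65 CPM). Bone matrix genes had a median of -0.21 at week 4, with Ibsp (bone sialoprotein) at -2.42, Pth1r at -2.11 and Alpl (alkaline phosphatase) at -1.64, and -0.03 at week 12. Of the matrix proteases, Mmp13 (-2.35) and Mmp2 (-2.19) were lower at week 4 (list median -0.22), and the median was 0.18 at week 12. Osteoclast regulators of stromal cells had medians of -0.08 and 0.82, and at week 12 Csf1 (1.59), Lgr4 (0.93), Cxcl12 (0.92) and Wnt5a (0.72) were higher. Mevalonate genes were higher in 18 of 22 cases at week 4 and 19 at week 12 (medians 0.11 and 0.37), interferon genes had a median of 0.57 at week 12, where Usp18 (1.48) and Isg15 (1.14) were highest, and the 5 measured genes of MHC class II presentation had a median of 0.41 at week 12. Skeletal stem and progenitor genes had a median of -0.19 at week 4 with Nt5e at -1.07 and Ctsk at -1.27, which became -0.83 when members needed at least 100 UMIs and -0.78 with cells thinned, so its size depends on the weakly expressed members. In the same way the interferon median of 0.17 at week 4 turned to -0.056 with cells thinned.

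The third comparison, of magnesium added to zoledronate, was the one the series title asks about. At week 4 the magnesium and zoledronate libraries were close, with a standard deviation of 0.17 over the log2 ratios of all genes against 0.49 at week 12. At week 12 cell cycle genes were higher in magnesium, with Mki67 at 43.3 against 15.5 CPM, and the matrix genes Col11a1, which encodes a collagen of cartilage, and Lum were lower, at 223 against 1916 CPM and 11.1 against 139 CPM. The secreted BMP antagonist Grem1 (1137 against 211 CPM) and the chemokine Ccl2 (831 against 211 CPM) were higher at week 12.

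The cell cycle list had medians of 0.11 at week 4, with 0 of 20 members at least 1.5-fold apart, and 1.03 at week 12, with 16 of 20 at least 1.5-fold and 10 at least 2-fold higher. Only 4 genes met the rule for higher at both weeks: Fos (1.08 and 1.17), the antiproliferative gene Btg2 (0.92 and 0.87), the membrane glycoprotein gene Emb (0.60 and 1.63) and the AP-1 gene Junb (0.60 and 0.62). Only Wfdc1, which encodes a secreted protease inhibitor-like protein, met it for lower (-0.64 and -1.20), so the lowest genes of each week were taken: the matrix gene Thbs4 (-2.62), Igfbp3 (-0.65) and Wfdc1 at week 4, and Cilp2 (-3.60), Lum (-3.53) and Col11a1 (-3.10) at week 12. Igfbp3 was on the other side at week 12 (1.03), and so was Thbs4 (59.9 against 33.7 CPM).

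Cartilage genes had medians of 0.25 and -0.87. At week 12, 5 of the 9 measured were at least 1.5-fold lower in magnesium, led by Col11a1, the matrix linker Hapln1 (-2.83), Comp (-1.31) and Sox9 (-0.92). Bone matrix genes had medians of 0.07 and -0.25, with Alpl at -1.31 and Pth1r, the parathyroid hormone receptor, at 1.20 at week 12. Fibrous matrix genes parted at week 12: Lum and Dcn (-2.89) were lower, and Vcan (1.51) and Thbs2 (1.33) higher, with a median of -0.16. The protease inhibitor Timp3 was lower (-4.19) and the plasminogen activator Plau higher (2.39), within a list whose median was 0.31. Skeletal stem and progenitor genes had medians of -0.09 and 0.54, with Grem1 (2.42) higher and Cd200 (-2.36) lower at week 12, and BMP and TGF beta genes medians of 0.04 and 0.19, with Nog, another BMP antagonist, at 2.03 and Bmp4 at -1.52. WNT genes differed both ways at week 12 (median 0.27), with Sfrp1 (3.67) and Wnt4 (3.39) higher and Wnt16 lower (-3.67). Osteoclast regulators had a median of 0.02 at week 4 and 0.94 at week 12, with Csf1 at 2.21, Wnt5a at 1.54, Cxcl12 at 1.10 and Il34 at -0.87. All 13 measured targets of cyclic AMP and CREB were higher in magnesium at both weeks (medians 0.14 and 0.62), among them Nr4a1 (1.13 and 1.23) and Pde4b (0.67 and 1.68). The immediate early and heat shock list, with Fos and Junb in common, was higher as well (medians 0.17 and 0.27). Calcrl was at 0.539 CPM (0.431 to 0.665) in magnesium and 0.141 CPM (0.0885 to 0.214) in zoledronate at week 12, and at 0.0806 and 0.135 CPM at week 4. Ramp1 was at 0.257 CPM in magnesium at week 12, but its 41 UMIs came from 9 of 8036 cells (0.112%), so a few cells carried this value. Ramp3 was at -0.33 at week 4 and higher in magnesium at week 12 (2.67). The list of CGRP and its receptors had medians of -0.02 and 0.43. Set against CGRP instead of zoledronate, Ramp3 in magnesium was lower at week 4 (-2.03) and higher at week 12 (1.15).

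Genes that carry magnesium across membranes differed both ways: the medians of the 13 measured were -0.02 and 0.06, and at week 12, 8 were higher and 5 lower, with Slc41a3 at 0.67, Slc41a2 at 0.49 and Cnnm2 at -0.55. Trpm7, a magnesium-permeable channel, was at 50.6 against 49.2 CPM at week 4 and 46.2 against 50.8 CPM at week 12. Focal adhesion and VEGF genes had medians of 0.00 and 0.20, with the fibronectin receptor subunit Itga5 at 1.12, angiogenic factors -0.04 and 0.06, with Vegfd (2.36) and Adm (1.91) higher at week 12, and mevalonate genes -0.04 and 0.27. The osteoclast resorption list had medians of 0.04 and 0.09, with Acp5 at 21.5 against 16.9 CPM and Ctsk at 137 against 124 CPM at week 12. The zoledronate libraries are the same as in the comparisons before, so these differences share their chance values.

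The fourth comparison set magnesium beside CGRP, both with zoledronate. At week 4 cell cycle genes were lower and fibrous matrix genes higher in magnesium than in CGRP, with Mki67 at 79.9 against 150.2 CPM and Dcn at 206 against 9.32 CPM. At week 12 cell cycle genes were alike, with Mki67 at 43.3 against 46.1 CPM, and Dcn and Lum lay the other way, at 46.9 against 179 CPM and 11.1 against 168 CPM. Grem1 and Igfbp3 were higher in magnesium at both weeks.

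All 20 cell cycle genes were lower in magnesium at week 4 (median -0.88), 15 of them at least 1.5-fold, whereas at week 12 the median was -0.01, with 10 members on each side and 0 at least 1.5-fold apart. By the rule, 15 of 2105 genes were higher in magnesium at both weeks. In ranked order they began with Grem1 (1.35 and 1.46), Igfbp3 (1.18 and 1.79) and the smooth muscle calponin gene Cnn1 (1.43 and 1.09). Next were the placental growth factor Pgf (1.03 and 1.25) and Ppp1r14a, an inhibitor of myosin phosphatase (1.02 and 0.92). Genes lower at both weeks were the scaffold gene Akap12 (-1.01 and -0.90), the WNT agonist Rspo1 (-1.08 and -0.72) and the translation factor Eif5a (-0.63 and -0.62). Fibrous matrix genes had medians of 0.82 at week 4, with 10 of 16 at least 1.5-fold higher, and -0.04 at week 12. Cartilage genes had medians of 0.36 and -0.56, with Comp at 1.66 at week 4 and Hapln1 (-2.17) and Col11a1 (-1.81) lower at week 12. Bone matrix genes were higher at week 4 (median 0.35), with Pth1r at 2.60, Ibsp at 1.97 and Alpl at 1.74, and had a median of -0.16 at week 12. WNT genes had medians of 0.43 and 0.12, interferon genes -0.13 and -0.37, and cyclic AMP targets 0.01 and 0.18. Fdps was at 365 against 426 CPM and 339 against 365 CPM at the 2 weeks. The median of the alternatively activated macrophage list at week 12 (-0.24) turned to 0.11 with cells thinned and 0.20 with members of at least 100 UMIs, so it had no settled direction.

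**Figure D2:**
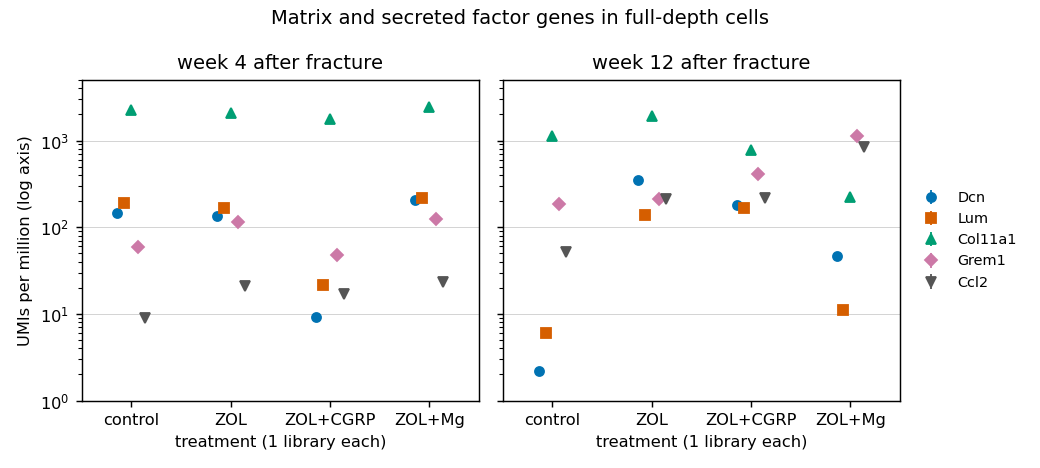
Expression of the matrix genes Dcn, Lum and Col11a1 and the secreted factor genes Grem1 and Ccl2 (CPM, log axis) in full-depth cells of the 4 treatments (1 library each) at weeks 4 and 12, with exact Poisson 95% intervals. At week 12 the control library had 2.19 CPM of Dcn and the magnesium library 1137 CPM of Grem1 and 831 CPM of Ccl2.

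The last comparison set week 12 against week 4 within each treatment. Col4a1, a collagen of basement membranes, was higher at week 12 in all 4 treatments, for example at 429 against 30.6 CPM in control, 228 against 35.7 CPM in CGRP and 331 against 35.0 CPM in magnesium. Most cartilage genes were lower at week 12 in all 4, with Comp, a matrix protein of cartilage and tendon, at 3.23 against 40.3 CPM in control and 7.51 against 56.5 CPM in magnesium. Cell cycle genes were lower at week 12 in zoledronate, CGRP and magnesium, with medians of -1.57, -1.59 and -0.56, while the control median was 0.06.

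Higher at week 12 in the 4 treatments (log2 ratios in the order control, zoledronate, CGRP, magnesium) were Col4a1 (3.77, 2.67, 2.64 and 3.21), Igfbp3 (1.58, 1.48, 2.55 and 3.16), Cnn1 (2.33, 1.43, 2.60 and 2.26), the growth factor Igf1 (1.70, 1.26, 4.24 and 2.56) and the TGF beta-induced gene Tsc22d1 (1.64, 1.34, 1.15 and 1.03). These were the first 5 of 11 genes that met the rule as higher. Lower were the opioid precursor Penk (-1.40, -3.26, -2.57 and -1.99), the annexin gene Anxa8 (-2.45, -1.27, -2.54 and -1.34), Spp1, which encodes the bone matrix protein osteopontin (-1.25, -0.97, -1.35 and -2.17), and Spats2l (-0.82, -0.64, -0.72 and -1.36). In the same order the cartilage medians were -0.98, -0.61, -0.49 and -1.31, with Hapln1 at -2.42, -2.12, -4.57 and -5.62 and Comp at -3.29, -0.79, -0.45 and -2.76. Bone matrix medians were -0.49, -0.24, 0.06 and -0.30, with Ibsp at -1.90, -2.78, 0.08 and -2.46. Fibrous matrix medians were -0.58, -0.21, 0.56 and -0.27: Dcn was lower at week 12 in control (-5.54) and magnesium (-2.11) and higher in zoledronate (1.40) and CGRP (4.12). Stem and progenitor medians were 0.28, 0.11, 0.74 and 0.81, with Grem1 at 3.09 in CGRP and 3.20 in magnesium. Ccl2 was higher at week 12 in all 4 (2.42, 3.28, 3.58 and 5.09), while the inflammatory list that holds it had medians of 1.22, 0.20, -0.33 and -0.03. Senescence and p53 genes had medians of 0.22, -0.02, 0.04 and -0.24, with the cell cycle inhibitor Cdkn2a at 1.59 and Ccng1 at 1.11 in control. With cells thinned, the cartilage median became -2.06 in control and -2.83 in magnesium, the bone matrix median of magnesium -0.996 and the inflammatory median of CGRP -0.99, and the alternatively activated macrophage median of control (0.20) became -0.61.

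The genes given whatever their values addressed the drug targets and bone resorption. In the order control, zoledronate, CGRP and magnesium, Fdps was at 475, 385, 426 and 365 CPM at week 4 and 369, 276, 365 and 339 CPM at week 12. Trpm7 was at 43.6, 49.2, 39.0 and 50.6 CPM and 50.1, 50.8, 44.3 and 46.2 CPM, and the tartrate-resistant phosphatase gene Acp5 at 9.81, 10.7, 7.44 and 12.6 CPM and 7.62, 16.9, 12.5 and 21.5 CPM. The protease gene Ctsk (cathepsin K) was at 50.8, 124, 135 and 137 CPM at week 12, and at 115 CPM in control, 126 CPM in zoledronate and 51.5 CPM in CGRP at week 4, when its log2 ratio of magnesium over zoledronate was 0.25. Ctsk thus had its lowest values in CGRP at week 4 and in control at week 12. Calcrl in control was at 0.0746 CPM (0.0372 to 0.133) and 0.166 CPM (0.105 to 0.249). Ramp1 was at 0.123 CPM in control at week 12 (0.0714 to 0.196) and 0.0806 CPM in magnesium at week 4 (0.0416 to 0.141), and was not listed in control at week 4.

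**Figure D3:**
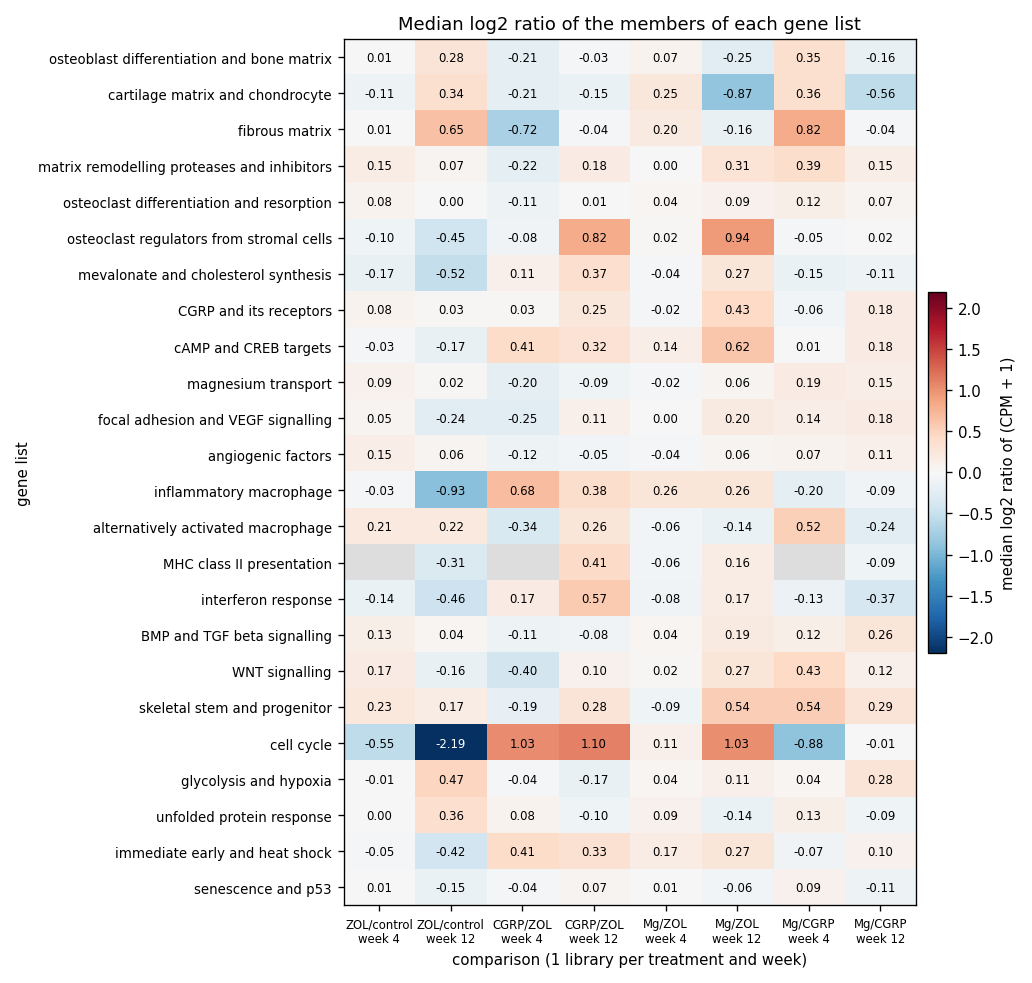
Median log2 ratio of CPM plus 1 over the measured members of 24 gene lists (vertical axis) in the 4 treatment comparisons at weeks 4 and 12 (horizontal axis), with red for higher and blue for lower in the library named first and grey where fewer than 3 members were measured. The cell cycle list stands out, at -2.19 for zoledronate over control and 1.03 for magnesium over zoledronate at week 12.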

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

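No test was chosen for the results of this part, either before or after they were seen. In each, the sign of a log2 ratio at week 12 was opposite to that at week 4 in the same comparison, or cells stood outside the comparisons. Each of these differences between weeks was not tested, since each value rests on 1 library per group.

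Between CGRP and zoledronate, Mmp2, which encodes a gelatinase that remodels matrix, was lower in CGRP at week 4 (-2.19) and higher at week 12 (1.03). Its expression was 63.5 against 292 CPM at week 4 and 505 against 247 CPM at week 12. Car9, a carbonic anhydrase induced by low oxygen, went the other way, higher at week 4 (1.07) and lower at week 12 (-1.87). Its expression was 94.9 against 44.6 CPM and 30.3 against 113 CPM. The alternatively activated macrophage list had a median of -0.34 at week 4, with Igf1 (-1.68) and Arg1 (-1.09) lower, and of 0.26 at week 12, with Il1rn (2.61) and Igf1 (1.31) higher. No macrophage cluster was found, so these values are of all full-depth cells.

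Between magnesium and zoledronate, the cartilage list had a median of 0.25 at week 4, with Hapln1 (0.66) and Comp (0.65) higher, and of -0.87 at week 12. Between magnesium and CGRP, the cartilage medians were 0.36 and -0.56, with Comp at 1.66 at week 4 and -0.65 at week 12. Dcn was higher in magnesium than in CGRP at week 4 (4.33) and lower at week 12 (-1.91), and Lum likewise (3.27 and -3.80). The alternatively activated macrophage list had medians of 0.52 and -0.24 in this comparison, but the value at week 12 turned to 0.11 with cells thinned to 1000 UMIs and 0.20 with at least 100 UMIs per member, so the opposite sign was lost in both settings.

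Outside the comparisons stood the cells of the 2 low-count clusters, 6.45% of all cells clustered. Cluster 3 held 3624 cells with a median of 2374 UMIs, 13.3% of the median of their own libraries, and cluster 13 held 864 cells with a median of 1611.5 UMIs, or 9.43%. No mitochondrial genes were listed by which to tell damaged cells from small ones, so these cells were given no type.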

How the results depend on the processing

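The tests that kept the low-count clusters in the ratios and that thinned cells to 5000 UMIs were chosen only after the data were seen. Among 3168 alternative values, 85 list medians and 11 gene ratios had the other sign. Most of these results lay near 0. A change of direction was counted only where a reported list median was at least 0.1 in size or a reported gene ratio at least 1.5-fold. By this count 6 changed, all list medians. The 11 gene ratios were of Trpm7 and Ctsk, at 0.06 or less in size. The largest shift of any of the 160 gene ratios was 0.32, for Cenpf with cells thinned to 1000 UMIs.

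With thinning, the median for cyclic AMP targets, zoledronate over control at week 12, turned from -0.17 to 0.13, and that for interferon genes, CGRP over zoledronate at week 4, from 0.17 to -0.056. The alternatively activated macrophage list turned from -0.24 to 0.11 with thinning and 0.20 with at least 100 UMIs per member for magnesium over CGRP at week 12, and from 0.20 to -0.61 and -0.40 for week 12 over week 4 in control. Thinning and the higher minimum leave fewer members in a list by construction.

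The cell cycle medians moved by more than their counting intervals in some settings. With TMM, DESeq2 and thinning in turn, zoledronate over control at week 12 was -2.06, -2.06 and -2.35. CGRP over zoledronate at week 4 was 1.06, 1.07 and 1.13, magnesium over zoledronate at week 12 was 0.97, 0.97 and 1.12, and magnesium over CGRP was -0.90, -0.91 and -0.99 at week 4 and -0.065, -0.067 and 0.080 at week 12. With thinning, CGRP over zoledronate at week 12 was 1.02 and magnesium over zoledronate at week 4 was 0.0954. For cartilage, week 12 over week 4 was -1.05, -1.04 and -2.06 in control. With thinning it was -0.86 in zoledronate, -0.95 in CGRP and -2.83 in magnesium, where at least 100 UMIs per member gave -1.89. Scaling moves every gene of a library alike. Thinning left 6 of the 9 measured cartilage members in control and 6 of the 10 in magnesium, so these medians are over fewer members. Thinned sums also hold fewer UMIs than the sums behind the counting intervals, so resampling noise alone can take a thinned median outside them. The cause of the other moves was not tested.

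Among the other values, gene ratios moved by more than their counting intervals in 81 of 160 cases with TMM, 84 with DESeq2 and 109 with thinning. They moved in 61 with equal weight per cell, 21 with the low-count clusters kept and 5 with the stricter filter. Leaving out the minimum of UMIs cannot change a gene ratio, so its 0 moves are no check. Thinned sums hold fewer UMIs than the sums behind these intervals. Resampling noise alone can thus take a thinned gene ratio or list median outside its interval, so the counts of moves with thinning do not measure dependence on processing. List medians moved in 72, 78 and 181 cases with TMM, DESeq2 and thinning, 72 with at least 100 UMIs, 26 with no minimum, 18 with the low-count clusters kept and 0 with the stricter filter, and 12 moved by over 1.5-fold, all with thinning or at least 100 UMIs. With thinning these included bone matrix, week 12 over week 4 in magnesium (-0.30 to -0.996), cartilage, CGRP over zoledronate at week 12 (-0.15 to -0.77), the inflammatory list, week 12 over week 4 in CGRP (-0.33 to -0.99) and magnesium over zoledronate at week 12 (0.26 to 1.02), the alternatively activated list, week 12 over week 4 in magnesium (0.20 to 0.95), and WNT genes, week 12 over week 4 in CGRP (0.34 to 1.60). The low-count share of the 8 libraries moved in 8 with the stricter filter, which removes cells with few UMIs by construction, in 3 each with Leiden resolution 2 and with 15 principal components, in 1 each with Leiden resolution 0.5 and with 4000 variable genes, and in 0 with doublets kept or every barcode. The share of cells with a UMI of Mki67 moved in all 8 libraries with depth. With cells thinned to 5000 UMIs it was 23.9% in control and 3.64% in zoledronate at week 12. Depth limits genes near the floor: Calcrl, Ramp1 and Csf1r rest on few UMIs, so their ratios were not interpreted.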

Other observations

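The TMM test of the cell cycle pattern, and the TMM test of the immediate early pattern without magnesium at week 12, were chosen only after the results were seen. The genes in the next paragraph were chosen after their values were seen, as were the patterns tested below. A further test of the cell cycle pattern, leaving out cluster 5, was written down but not run, because cluster 5 makes up most of the zoledronate library of week 12 and cell cycle genes help to define the clusters.

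Single libraries of week 12 stood apart in single genes. In control at week 12, Akap12 was at 1649 CPM against 154 to 334 elsewhere, Il1rl1, the receptor of interleukin 33, at 543 against 61.0 to 106, and the small heat shock gene Cryab at 881 against 77.7 to 349. In CGRP at week 12, Wfdc18 was at 211 CPM against 0.645 to 11.2 elsewhere. In magnesium at week 12, the chemokine Ccl7 was at 688 CPM against 3.35 to 230.2 elsewhere, G0s2 at 572 against 4.07 to 187, and Hsd11b1, which activates glucocorticoids, at 194 against 6.75 to 88.7. Pitx1, a transcription factor of hindlimb identity, was at 1.18 CPM in magnesium at week 12 against 21.8 to 52.4 elsewhere, while Hoxc10, another hindlimb gene, was at 63.7 to 115 CPM over all 8 libraries.

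Cell cycle genes were lower in zoledronate than in control at week 12 (median -2.19). A few genes taking most of the counts would lower all other genes alike, and TMM factors, which remove such a shift, left the median at -2.06, which argues against it as the whole cause. The animals or culture dishes of 1 library stay open, since the design holds 1 library per treatment and week. An effect of zoledronate on division of callus cells is a further open explanation and was not tested apart from them. The cells had spent 24 h in culture, so either may have acted in the animal or in the dish.

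Immediate early genes, such as Fos and Junb, which are also cyclic AMP targets, were higher in CGRP and magnesium than in zoledronate, with medians of 0.56 and 0.34 for CGRP and 0.54 and 0.13 for magnesium at weeks 4 and 12. Handling stress would raise heat shock genes too: their medians in the same order were 0.09, 0.28, -0.03 and 0.56, and the highest, 0.56, was in the comparison where the immediate early median was lowest. A few genes taking most of the counts would shift most genes alike, and TMM factors remove such a shift. They left the immediate early medians at 0.58 and 0.33 for CGRP, and 0.54 and 0.10 for magnesium, at weeks 4 and 12. The bounds set beforehand were below 0.2 or above 0.5 in each of the 4 comparisons, so this test could not decide. The later test, without magnesium at week 12, had 0.33 as its lowest value, above a bound of 0.2 also chosen afterwards. No conclusion is drawn from that bound. The TMM shifts, however, were only 0.026 and -0.006 for CGRP and 0.003 for magnesium at week 4. Shifts so small beside the medians argue against this explanation there. For magnesium at week 12 the shift was -0.061 beside a median of 0.13, so it stays open for that comparison. Members at week 12 ranged from -0.93 to 1.48 for CGRP and from -0.51 to 1.26 for magnesium. Handling stress stays open, as does an effect of the treatments. Over control, the immediate early and heat shock list had medians of -0.05 for zoledronate, 0.39 for CGRP and 0.23 for magnesium at week 4. At week 12 they were -0.42, -0.16 and -0.03 in the same order. For this list, which also holds the heat shock genes, the medians of CGRP and magnesium thus lay above control at week 4. At week 12 the TMM shifts over control were 0.13 for CGRP and 0.075 for magnesium. These are of the size of the 2 medians, so no direction is read from them at week 12. Medians of the immediate early members alone were not taken over control.

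RT1-A1 and RT1-A2, class I genes of the rat major histocompatibility complex, were each near absent in 1 library: RT1-A1 was at 0.970 CPM in zoledronate at week 12 and RT1-A2 at 0.908 CPM in magnesium at week 12, against 5.41 to 39.3 and 8.10 to 66.3 CPM elsewhere. If a library held few animals with different gene copies, cells with 1 gene would hold the other less often. At 5000 UMIs per cell the odds ratio was below 0.8 in 2 libraries, 0.278 (0.151 to 0.509) in control at week 12 and 0.699 (0.522 to 0.938) in CGRP at week 4. It was between 0.806 and 1.37 in the other 6. The 2 highest were in the libraries where 1 gene was near absent, which cannot bear this test. They were 1.31 (0.760 to 2.27) in zoledronate at week 12, with 20 cells holding both genes, and 1.37 (0.649 to 2.88) in magnesium at week 12, with 9. The remaining values reached at most 1.02. With values on both sides of 0.8, this stays open. Reads shared between the copies would leave their sum alike, and its highest value was 2.73 times its lowest, between the bounds of 1.5 and 3 set beforehand, so this stays open too. No biological explanation beyond the animals themselves was tested.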
